A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

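The deposited material covers 10 libraries of Saccharomyces cerevisiae. For ChIP, chromatin of formaldehyde-fixed, exponentially growing cells was precipitated with antibodies to H3K4me3 or H3K79me3, and the DNA was amplified by ligation-mediated PCR and sequenced as single reads, per the labels' protocols. Whole cell extract of each strain was sequenced as the control. For RNA, polyA libraries were made with a kit that does not mark strand, per the labels' protocols, so antisense RNA and overlapping genes were not told apart. The processed files hold aligned reads, 1 per line, with the score of each read, and the deposited score was the same in every line and carried no measurement. The measurement used here was the number of reads per region. Per the submitters' processing notes, the tools were CASAVA 1.8, Bowtie 0.12.7 and TopHat 1.3.1 and the genome build was sacCer2. Filters on reads were not given in the sources used here. Reads were 45 bp long. RNA reads were absent from near-identical repeats while ChIP reads were present in low-copy repeats, so values of paralogs, such as the paired ribosomal protein genes, are uncertain.

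Gene spans of the files' own build were not at hand. Gene names and spans were taken from the RefSeq gene table of assembly R64, which is another build than that of the files. The distance between the builds was therefore measured from the reads themselves, at transfer RNA genes, whose near-identical copies leave runs in which no ChIP read starts. Runs of fitting length were sought up to 500 bp to either side, and a run counted as an anchor only where another run of the chromosome gave a distance within 20 bp of its own. A chromosome was used where it had at least 2 anchors and every anchor lay within 20 bp of its place in the table. That held for 14 of 16 chromosomes, with 92 anchors and distances from -12 to 6 bp. On 7 of these 14 chromosomes, 10 of the 102 runs were left out as no other run shared their distance, which was 77 to 448 bp in either direction. Of these 10, 3 lay at the place of another transfer RNA gene. For the others no cause was found. An anchor was found on both sides of 7 of the 10, and on chromosomes X, XIV and XV the last run lay beyond the last anchor, so a local shift there is not excluded. Chromosome I had no anchor, and chromosome XI had a distance of -358 bp, so neither was analysed. Between and beyond anchors a distance was not measured, so a gene there could be misplaced by an unmeasured amount. Windows were kept 20 bp inside both ends of each coding span. No position of the table is printed and no coordinate was converted. Of 6021 protein-coding genes in the table, 5590 lie on the chromosomes used. The minimum number of anchors was lowered from an intended 3 after chromosome VI was seen to have 2, and transfer RNA genes replaced the intended comparison of spliced reads with annotated introns because the table lists no introns.

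RNA reads were counted in gene windows, giving 4851688, 9129971, 7400904 and 5137999 reads in wild-type replicates 1 and 2 and deletion replicates 1 and 2. Genes were kept with at least 10 reads at the median library size in 2 libraries and at least 15 reads in all. As planned for files that hold alignments and no count column, the test was limma-voom (limma 3.58.1 in R 4.3.3) with TMM scaling factors. It was run on the 2 wild-type and 2 deletion libraries with no covariate, and p-values were adjusted by the Benjamini-Hochberg method. CPM values were computed here from the counts and the TMM-scaled library sizes. Replicates differed by more than counting error, with a chi-square per degree of freedom of 20.6 in the wild type and 17.3 in the deletion, so each library was kept as its own replicate. Gene lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over 30 lists. On simulated libraries of 5166 genes with 200 changed, this RNA comparison recovered 23.4% of genes changed 1.5-fold, 82.2% of those changed 2-fold and 99.1% of those changed 4-fold, with 5.52% false calls. These genes were changed independently of each other. With 200 true changes the adjusted threshold is easier to pass than in the main fit, which called 2 genes. The rates are therefore not rates for the real libraries.

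Introns were taken from gaps spanned by at least 20 RNA reads inside genes. The intron test used limma on the log2 ratio of intron to exon reads per bp, with 0.5 reads added, in genes with at least 20 intron reads. The test of 3' to 5' reads, split at the midpoint of each gene, used limma on genes of at least 1000 bp with a mean of at least 100 reads.

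For ChIP, read 5' ends were moved 75 bp downstream, each library was scaled to its nuclear read total, and the precipitate was divided by the whole cell extract of the same strain. Profiles used genes of at least 1000 bp in steps of 50 bp, with reads summed over genes before the division. Changes per gene used windows with at least 100 reads in both precipitates, and for the genes named at least 100 in both extracts. Intervals of single genes are the log2 ratio plus or minus 1.96 counting standard errors, and those of shares and regions come from 200 Poisson resamples, in place of exact Poisson intervals on the counts. On simulated libraries the 95% interval held the true value in 95.3% of genes for H3K4me3 and 94.7% for H3K79me3. With 1 library per strain and mark no test was made; the median of a gene list was placed among 10000 random lists of the same size matched on signal. CHD1 itself was left out of all ChIP summaries, a choice made after its reads in the deletion libraries were seen.

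Chosen before the data were examined were the tests, 30 gene lists of named genes, the windows, the alternatives and the genes to name. These genes were CHD1, the 12 largest rises and 12 largest falls past the threshold, up to 4 members of each list (those with the smallest adjusted p, or the 2 most abundant where none passed), and the 5 largest rises and falls per mark. Genes named because they passed adjusted over a list alone, such as HSP26 or ADE2, and further genes given as examples, were chosen after their values were seen. Alternatives were median-of-ratios size factors, no filter on low counts, the replicate number as a block, each replicate left out, 1 read per position, shorter windows, overlapping genes left out and a fold threshold for RNA. For ChIP they were 1 read per position, no read shift, no division by extract, another scaling and other gene sets. After the data were seen 3 alternatives were added, limma-trend among them. The 4 RNA libraries share 1 lane of a flow cell, and the 6 ChIP libraries share another flow cell, per the read names in the deposited alignments. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.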

Results

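The libraries came from 2 strains of budding yeast, the wild type FM391 and the same strain with CHD1 deleted. Chd1 is an ATP-dependent chromatin remodeller that binds transcribed genes. The title of the study names H2B monoubiquitination and the re-assembly of nucleosomes, and both histone marks measured here, trimethylated lysine 4 and lysine 79 of histone H3 (H3K4me3 and H3K79me3), are known to depend on H2B ubiquitination. The libraries answer where each mark lay along genes with and without Chd1, and which RNAs differed. For chromatin immunoprecipitation (ChIP), 1 library per strain was made for each mark and 1 for whole cell extract, from cultures at an optical density of 1.0. For RNA, 2 polyA libraries per strain were made from cultures at an optical density of 0.8. Nuclear reads numbered 6742369 in the wild-type extract, 9257591 for H3K79me3 and 6922086 for H3K4me3. In the deletion they numbered 7752502 in the extract, 8594123 for H3K79me3 and 6427265 for H3K4me3. RNA reads inside gene windows numbered 4851688 and 9129971 in the wild type and 7400904 and 5137999 in the deletion. The labels do not say that the 2 RNA libraries of a strain came from separate cultures, so p-values measure the spread between these libraries, which may be technical. All intervals cover counting error only.

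CHD1 itself (YER164W) had 468 and 1030 RNA reads in the wild-type libraries and 3 and 1 in the deletion libraries. At equal depth the deletion held 0.298% of the wild-type reads of CHD1 (exact 95% interval 0.0810 to 0.764). The whole cell extract of the deletion held 16 reads inside CHD1 against 2080 in the wild type, which at equal depth is 0.669% (exact 95% interval 0.382 to 1.09). Reads inside CHD1 matched the genotype labels in all 10 libraries. Other genes used to mark strains gave 0 reads for LEU2, URA3 and MET17 in all 4 RNA libraries, which allows at most 3 reads per library. The a-cell genes STE2, the receptor for alpha-factor, and BAR1, the protease that degrades alpha-factor, were read in all 4 libraries (STE2 at 1028 ± 83.9 and 1122 ± 97.9 CPM, SD, n = 2 per strain).

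In RNA, CHD1 fell by 8.20 on the log2 scale (SE 0.45, limma-voom adjusted p = 0.00237), from 107 ± 15.5 to 0.379 ± 0.144 CPM (SD, n = 2 per strain). YGP1 (YNL160W), which encodes a secreted cell wall glycoprotein induced when nutrients run out, rose by 2.98 on the log2 scale (SE 0.23, limma-voom adjusted p = 0.0102), from 89.3 ± 27.6 to 687 ± 107 CPM. Both deletion libraries lay above both wild-type libraries for YGP1. These were the 2 genes of 5166 tested that passed the threshold of 0.05. At an unadjusted p under 0.05 there were 623 genes, 410 higher and 213 lower in the deletion. Genes whose 2 deletion libraries both lay on one side of both wild-type libraries numbered 2272, or 44.0%, against 33.3% if all orders of the libraries were equally frequent. All genes share the same 4 libraries and are not independent, so this difference is not a test.

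The first principal component of log2 CPM held 50.9% of the variance and put the wild-type libraries at -6.36 and -16.0 and the deletion libraries at 14.8 and 7.51. The SD over genes of the difference between replicates was 0.36 in the wild type and 0.31 in the deletion on the log2 scale, against 0.32 for the difference between the strains' means. PHO84, the high-affinity phosphate transporter, shows that spread: it stood at 406 and 3427 CPM in the wild-type libraries and at 1523 and 946 CPM in the deletion libraries. The number of changed genes depended on single libraries: it was 5 without wild-type replicate 1, 3 without deletion replicate 1 and 17 without deletion replicate 2. With 1 read kept per start position it was 7 and the fold change of YGP1 was 1.59 on the log2 scale, and with windows shortened by 50 bp at each end it was 5.

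Stress genes stood higher in the deletion. Of 31 measured environmental stress genes, 29 had a positive log2 fold change, with a list median of 0.58 (camera adjusted p = 9.2e-12 with a preset correlation of 0.01; adjusted p = 0.685 with an estimated correlation). Median levels of the list were 33.1 and 41.1 CPM in the wild-type libraries and 62.8 and 49.0 CPM in the deletion libraries. Over all genes 1 member rose, YGP1, and adjusted over the list alone 13 rose and 0 fell. Among these 13 were the heat shock genes HSP26, a small chaperone (log2 1.49, SE 0.28), HSP78, a mitochondrial disaggregase (0.72, SE 0.13), and HSP104, its cytosolic counterpart (0.58, SE 0.12). GLK1, encoding glucokinase, went from 169 ± 38.2 to 333 ± 57.3 CPM (SD, n = 2 per strain), and TPS2, encoding trehalose phosphate phosphatase, from 113 ± 0.947 to 168 ± 17.8 CPM. HSP12 had a log2 fold change of 1.84 (SE 0.89) and did not pass.

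Markers of stationary phase moved with the stress genes and share members with them. Of 7 measured markers 6 had a positive fold change, with a median of 0.78 (camera adjusted p = 0.0170; adjusted p = 0.730 with an estimated correlation). The median was 0.45 without wild-type replicate 2, and 0.26 without the low-count filter, which tests more genes. Adjusted over the list alone 3 rose, namely GRE1 (log2 1.21), FMP45 (0.78) and HSP26, while over all genes 0 did by limma-voom or limma-trend. Of these 3, GRE1 and HSP26 also stand in the stress list. Of 35 genes of the TCA cycle and respiration 28 had a positive fold change, with a median of 0.19 (camera adjusted p = 0.000735; adjusted p = 0.905 with an estimated correlation), and this call ended without deletion replicate 1 (median 0.022, camera adjusted p = 0.861), while the median was 0.36 without deletion replicate 2 and 0.10 with 1 read per position. ACO1, encoding aconitase, stood at 706 ± 205 CPM in the wild type and 1081 ± 187 CPM in the deletion (SD, n = 2 per strain), and ATP2, a subunit of the mitochondrial ATP synthase, at 1381 ± 228 and 1170 ± 223 CPM. Of 20 genes of nitrogen and arginine catabolism 17 had a positive fold change, with a median of 0.24 (camera adjusted p = 0.00516; adjusted p = 0.888 with an estimated correlation). That call ended without wild-type replicate 1 (median 0.14, camera adjusted p = 0.0573) and without deletion replicate 2 (0.14, 0.0801).

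Genes of ribosome biogenesis stood lower in the deletion. Of 41 measured members 40 had a negative fold change, with a median of -0.24 (camera adjusted p = 1.2e-11; adjusted p = 0.556 with an estimated correlation), and 0 passed adjusted over the list alone or over all genes by limma-voom. With 1 read per position the median was -0.12 (camera adjusted p = 2.2e-06). NOP1, the methyltransferase of box C/D small nucleolar particles, stood at 1402 ± 124 CPM in the wild type and 1249 ± 12.6 CPM in the deletion (SD, n = 2 per strain). NSR1, encoding nucleolin, stood at 1269 ± 26.9 and 1119 ± 19.5 CPM. Median levels of the list were 307 and 295 CPM in the wild-type libraries and 258 and 254 CPM in the deletion libraries. The genes of the ribosomal proteins themselves differed by little: 91 of 131 had a negative fold change, with a median of -0.062 (camera adjusted p = 0.0192; adjusted p = 0.905 with an estimated correlation), and this call ended without wild-type replicate 1 (median 0.016), without deletion replicate 2 (0.055) and with 1 read per position (-0.013), while the median was -0.13 without wild-type replicate 2 and -0.17 without deletion replicate 1.

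Genes for the synthesis of purines, pyrimidines and phospholipids stood lower as well. Of 23 measured genes 19 had a negative fold change, with a median of -0.32 (camera adjusted p = 1.1e-07; adjusted p = 0.556 with an estimated correlation), and with 1 read per position the median was -0.11 (camera adjusted p = 9.8e-05). Adjusted over the list alone 7 fell and 1 rose, and over all genes 0 passed by limma-voom. The 7 that fell all act in purine synthesis, with log2 fold changes of -0.85 for ADE2, -0.73 for ADE17, -0.66 for ADE57, -0.58 for ADE6, -0.56 for ADE12 and -0.52 for ADE4, and of -0.57 for IMD4, an IMP dehydrogenase of guanine nucleotide synthesis. The gene that rose was OPI3 (log2 0.41), a methyltransferase of phosphatidylcholine synthesis. URA2, which starts pyrimidine synthesis, stood at 1500 ± 313 CPM in the wild type and 1167 ± 120 CPM in the deletion (SD, n = 2 per strain). Of 48 genes of amino acid biosynthesis 37 had a negative fold change, with a median of -0.15 (camera adjusted p = 0.00204; adjusted p = 0.905 with an estimated correlation), and the call ended without wild-type replicate 2 (median -0.059, camera adjusted p = 0.338), without deletion replicate 2 (-0.10, 0.0801) and with 1 read per position (-0.056, 0.163). HOM3, the aspartate kinase that starts threonine and methionine synthesis, fell adjusted over the list alone, from 448 ± 61.5 to 177 ± 25.1 CPM. Of 24 cell cycle regulators 19 had a negative fold change, with a median of -0.18 (camera adjusted p = 0.0192; adjusted p = 0.905 with an estimated correlation), 0 passed adjusted over the list alone, and the call ended without wild-type replicate 2 (median -0.076, camera adjusted p = 0.213) and without deletion replicate 1 (0.0081, 0.861), while the median was -0.31 without deletion replicate 2.

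**Figure D1:**
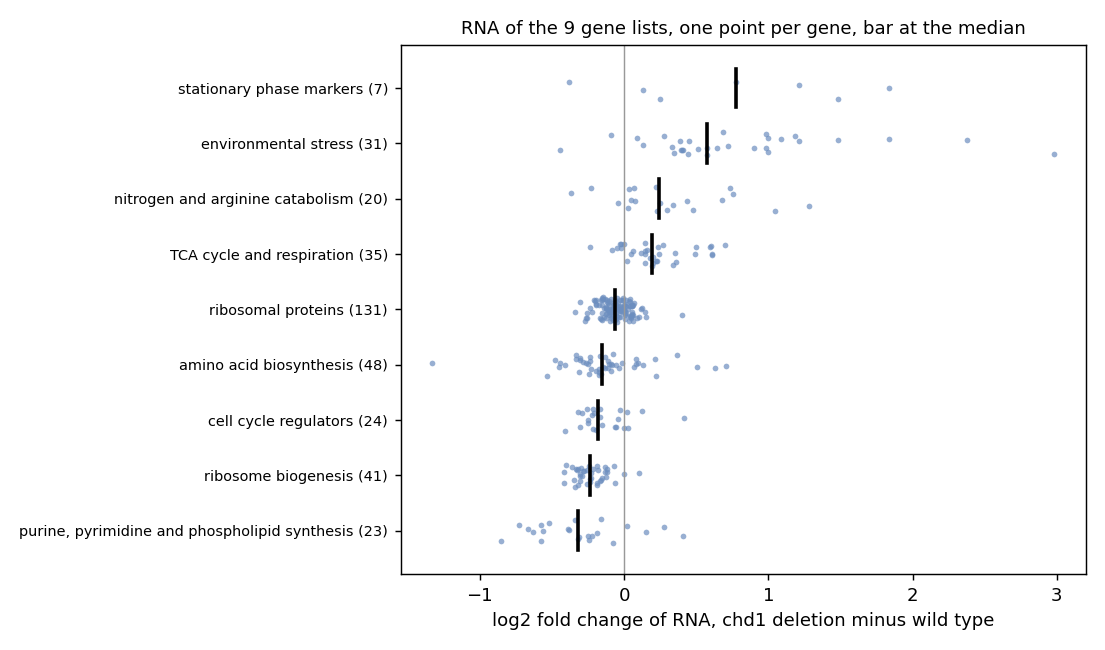
Log2 fold change of RNA (chd1 deletion minus wild type, horizontal axis) for the measured members of the 9 gene lists with a camera adjusted p under 0.05, with 1 point per gene, the number of genes in brackets and a bar at each list's median. The medians run from -0.32 for purine, pyrimidine and phospholipid synthesis to 0.78 for stationary phase markers, and the point farthest to the right is YGP1 at 2.98.

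Genes of the machinery around Chd1 had list medians near 0 in RNA. Of 21 measured genes of chromatin remodelling ATPases 1 passed by limma-voom, CHD1 itself, over all genes and over the list alone. The list's median was -0.058 (camera adjusted p = 0.528), and it was -0.10 without deletion replicate 2 and 0.045 without deletion replicate 1. CHD1 is a member, so its deletion alone pulls this list test downward. Lists for H2B ubiquitination (16 genes), histone genes (10), histone chaperones (18), the SAGA and SLIK complexes (16), RNA polymerase II elongation (18) and silencing (12) had medians between -0.048 and 0.093 in the main fit and between -0.14 and 0.17 with 1 library left out. CTR9, a subunit of the Paf1 complex, stood at 182 ± 12.9 CPM in the wild type and 159 ± 1.45 CPM in the deletion (SD, n = 2 per strain). SET1, the H3K4 methyltransferase, stood at 102 ± 4.31 and 97.1 ± 5.25 CPM. In the H3 methylation list (12 genes, median -0.030, camera adjusted p = 0.965; -0.039 to 0.0014 with 1 library left out), JHD2, which encodes the H3K4 demethylase, rose adjusted over the list alone, from 17.5 ± 0.880 to 29.9 ± 0.672 CPM, with an adjusted p of 0.221 over all genes by limma-voom.

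Other metabolic and cell type lists gave no call by camera in the main fit. Glycolysis (14 genes) had a median of 0.11, and TDH1, an isoform of glyceraldehyde-3-phosphate dehydrogenase, rose adjusted over the list alone, from 38.1 ± 21.0 to 151 ± 70.2 CPM (SD, n = 2 per strain), while PDC1, pyruvate decarboxylase, stood at 25415 ± 5177 and 23876 ± 1126 CPM. In hexose transport and galactose use (20 genes, median 0.21), SUC2, encoding invertase, fell adjusted over the list alone, from 208 ± 14.6 to 139 ± 12.4 CPM. In subtelomeric families (22 genes, median 0.20), TIR1 (log2 1.71; 1.06 to 2.22 with 1 library left out, 0.99 with 1 read per position) and TIR3 (1.02), encoding cell wall mannoproteins, rose adjusted over the list alone, and COS10 fell by 0.87. That list was drawn by family name and not by position, so its members need not lie near chromosome ends. Medians were 0.028 for the phosphate response (19 genes), -0.10 for the iron regulon (20), 0.053 for sulfur assimilation (23), -0.060 for ergosterol synthesis (24), 0.16 for the pheromone response (23), 0.036 for haploid markers (8), 0.11 for meiosis and sporulation (20), -0.099 for selectable marker genes (5) and -0.0074 for intron-containing genes (154). The alpha-cell genes SAG1 and MF(ALPHA)2 stood at 54.5 ± 4.86 and 2.78 ± 1.42 CPM in the wild type and at 64.7 ± 1.81 and 4.63 ± 0.928 CPM in the deletion (SD, n = 2 per strain). The a-cell markers (6 genes) had a median of 0.46 with a camera adjusted p of 0.0544 (adjusted p = 0.905 with an estimated correlation), and were called with median-of-ratios factors (0.0491), with overlapping genes left out (0.0465), without wild-type replicate 1 (0.000525) and without deletion replicate 2 (0.0332). Their median ran from 0.037 (without wild-type replicate 2, camera adjusted p = 0.752) to 0.73 (without wild-type replicate 1) with 1 library left out, and was 0.098 with 1 read per position (camera adjusted p = 0.164). Medians of the other lists moved widely too when 1 library was left out. The phosphate response ran from -0.71 without wild-type replicate 1 to 0.60 without wild-type replicate 2. Intron-containing genes ran from -0.098 without deletion replicate 1 to 0.081 without deletion replicate 2. The iron regulon had medians below 0 without wild-type replicate 1 (-0.57) and without deletion replicate 2 (-0.53), and above 0 without wild-type replicate 2 (0.22) and without deletion replicate 1 (0.21). The pheromone response ran from -0.041 without wild-type replicate 2 to 0.22 without wild-type replicate 1, and ergosterol synthesis from -0.16 without wild-type replicate 1 to -0.010. Glycolysis ran from -0.021 without deletion replicate 1 to 0.22 without deletion replicate 2, and hexose transport and galactose use from 0.14 to 0.28 without deletion replicate 2. Subtelomeric families ran from -0.0070 to 0.22, haploid markers from -0.078 to 0.12, meiosis and sporulation from -0.031 to 0.13, sulfur assimilation from -0.0053 to 0.088 and selectable marker genes from -0.23 to -0.0034. The alpha-cell markers, too low to be tested as a list in the main fit, were called higher without the low-count filter (camera adjusted p = 0.0362 with a preset correlation of 0.01).

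Within genes, neither the intron reads nor the balance of 3' to 5' reads gave a call. Introns were sought because splicing takes place while genes are transcribed. Of 94 genes with enough intron reads, 70 of them ribosomal protein genes, 0 changed by limma in the ratio of intron to exon reads, with 1 gene at an unadjusted p under 0.05. The ratio was lower in the deletion in 76 genes and higher in 18, with a median log2 difference of -0.42, which ran from -0.89 to -0.026 with 1 library left out and was -0.057 without ribosomal protein genes. The median ratio of intron to exon density was 1.16% and 2.26% in the wild-type libraries and 0.927% and 1.64% in the deletion libraries (two-sided exact permutation test, p = 0.667, where the smallest p that 4 libraries allow is 0.333). The ratio of reads in the 3' to the 5' part of genes, split at the midpoint, to which transcripts that start inside genes would add, was tested in 3008 genes of at least 1000 bp. Of these 0 changed by limma, with 178 at an unadjusted p under 0.05, 127 higher and 51 lower in the deletion. The median log2 ratio was 0.38 and 0.35 in the wild-type libraries and 0.40 and 0.38 in the deletion libraries (two-sided exact permutation test, p = 0.667).

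H3K4me3 lay over gene starts in both strains, and in profiles from the start codon it declined sooner in the deletion. With reads summed over genes of at least 1000 bp, enrichment over extract peaked 150 to 200 bp after the start codon in the wild type, at 2.46. In the deletion it peaked 100 to 150 bp after the start codon, at 2.40. Upstream of the start codon the deletion stood higher, with a log2 ratio of 0.20 at 150 to 100 bp before it (enrichment 0.959 and 1.10). Past the peak the deletion stood lower, most of all 500 to 550 bp into genes, where enrichment was 1.24 in the wild type and 0.898 in the deletion (log2 ratio -0.46), and at 950 to 1000 bp the values met at 0.638 and 0.635. Shares were taken over the 3315 genes with extract reads in both parts. The first 500 bp of the median gene held 53.2% of its H3K4me3 signal in the wild type (resampling interval 52.9 to 53.4) and 51.6% in the deletion (51.3 to 51.9), a difference of -1.60 percentage points (-1.91 to -1.16). That difference was -1.02 with 1 read per position, -2.52 without division by extract and -3.19 in genes of at least 2000 bp. By this share, relatively more of the signal lay past 500 bp in the deletion, so the share does not show a shorter reach into genes. Between the first and the last 500 bp, enrichment was 0.661 in the wild type and 0.607 in the deletion. The log2 ratio there was -0.12, close to the -0.11 of the first 500 bp. Only in the last 500 bp did the deletion stand higher, at 0.695 against 0.647 in the wild type, both below the level of the extract.

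H3K79me3 lay nearer to gene starts in the deletion. Enrichment peaked 700 to 750 bp after the start codon in the wild type, at 1.39, and 250 to 300 bp after it in the deletion, at 1.44. The first 500 bp of the median gene held 27.5% of its signal in the wild type (resampling interval 27.3 to 27.7) and 33.4% in the deletion (33.0 to 33.5), a difference of 5.81 percentage points (5.46 to 6.09). Enrichment in the first 500 bp was 1.18 in the wild type and 1.36 in the deletion, and in the last 500 bp it was 1.05 and 0.863, so that the log2 ratio ran from 0.20 at the start through -0.14 between the ends to -0.28 at the end of genes. Before the start codon the log2 ratio was larger, at 0.35 from 150 to 100 bp upstream. Enrichment there was 0.520 in the wild type and 0.663 in the deletion. Each mark and strain had 1 library, so these profiles have no replicate check and no test. Without a spike-in, the overall amount of either mark was not measured, and without a library for unmodified H3 the level of a mark per nucleosome was not measured.

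**Figure D2:**
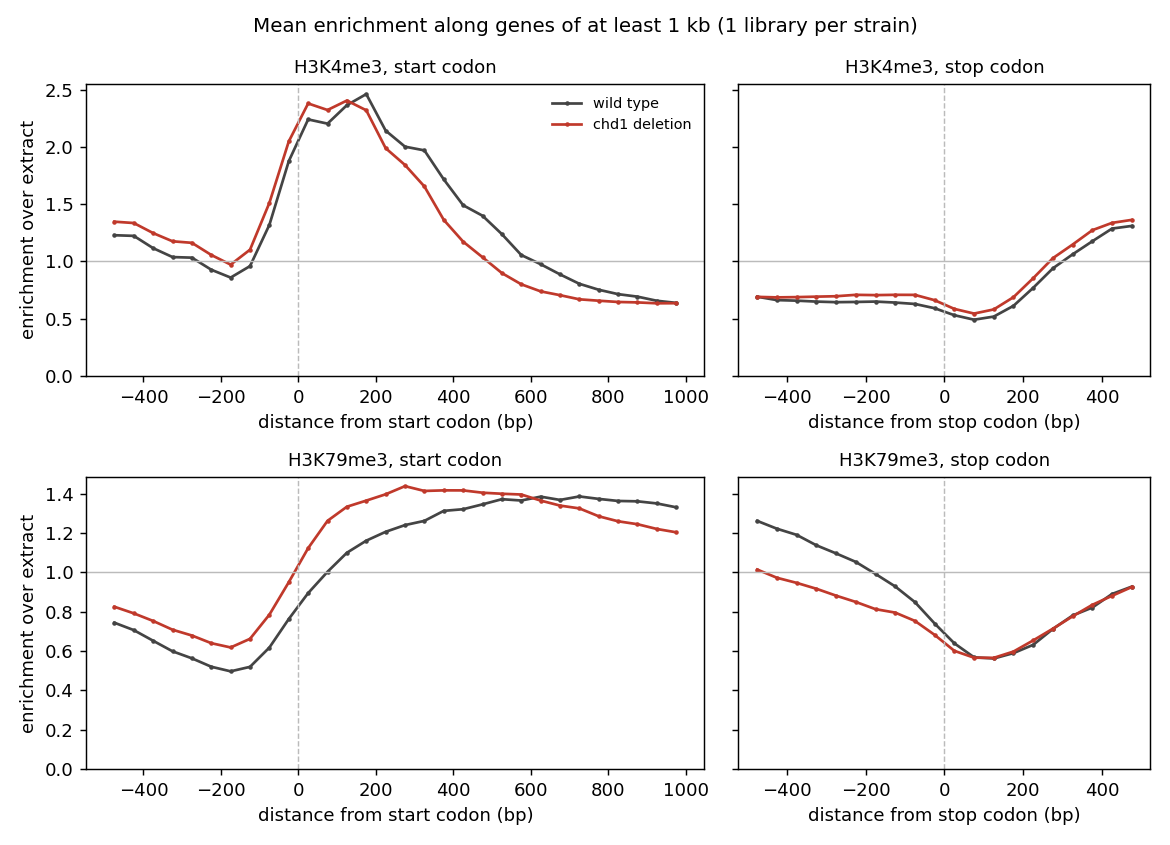
Enrichment over whole cell extract (vertical axis, a ratio of reads summed over genes) in 50 bp steps around the start codon and the stop codon of genes of at least 1 kb, for H3K4me3 in the upper row and H3K79me3 in the lower row, with 1 library per strain. The H3K4me3 lines part after the peak, at 1.24 and 0.898 near 500 bp, and the H3K79me3 peak lies at 250 to 300 bp in the deletion and at 700 to 750 bp in the wild type.

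Gene by gene, H3K4me3 around the start codon (100 bp before it to 500 bp after it) was lower in the deletion at long genes and at genes with much wild-type RNA. Median log2 changes were 0.17, 0.057, -0.014 and -0.084 from the shortest to the longest quartile of gene length, and 0.13, 0.068, -0.0024 and -0.12 from the lowest to the highest quartile of wild-type RNA. RNA quartiles were cut on CPM per gene, not divided by gene length, so RNA level and length were not separated. The shortest quartile held genes of 51 to 708 bp, and in genes shorter than 500 bp the window ran past the stop codon. The trend with length therefore cannot be told apart from the reach of the window. Over 5494 genes the SD of the change was 0.29 on the log2 scale, against 0.15 from counting error, and 26 genes were over 2-fold lower and 5 over 2-fold higher. The lowest were RPO21, the largest subunit of RNA polymerase II (log2 -1.61, counting interval -1.93 to -1.30, with 628 and 194 reads), FMP25 (-1.61), SEC39 (-1.45), URA2 (-1.37) and WHI4 (-1.37). With 1 read kept per position RPO21 stood at -1.28 and FMP25 at -1.13. The highest were SPL2 (log2 1.18, counting interval 0.88 to 1.48) and PHM6 (1.03), both of the phosphate response, then AIM11 (1.01), DCG1 (1.01) and YGL194C-A (1.01). Phosphate response genes also differed between RNA libraries of 1 strain: in the wild type PHO84 stood at 406 and 3427 CPM and VTC3 at 218 and 939 CPM. With 1 ChIP library per strain, the rises of SPL2 and PHM6 cannot be told apart from such variation.

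Among the gene lists, H3K4me3 was lower at ribosome biogenesis genes (41 genes, median -0.18, below all 10000 random lists matched on signal), cell cycle regulators (24 genes, median -0.20, percentile 0.01) and amino acid biosynthesis genes (48 genes, median -0.11, percentile 0.23). It was higher at histone genes (10 genes, median 0.30, percentile 99.8), genes of the TCA cycle and respiration (35 genes, median 0.15, percentile 99.5) and a-cell markers (6 genes, median 0.43, percentile 99.2). Ribosomal protein genes had a median of -0.051 in this window around the start codon (132 genes, percentile 3.63). These percentiles describe the libraries compared and are not tests.

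For H3K79me3 over whole coding regions, ribosomal protein genes stood out as lower in the deletion. They were not lower in this mark alone, as over the same regions their median log2 change of H3K4me3 was -0.46. Their median log2 change of H3K79me3 was -0.41 (129 genes), below all 10000 random lists matched on signal, whose median was 0.11. RPL24B (log2 -1.07, counting interval -1.42 to -0.72), RPL24A (-0.98) and RPS25B (-0.91) were among the 5 lowest of all genes, with HAC1, the transcription factor of the unfolded protein response (-1.11, counting interval -1.35 to -0.88), and YLR358C (-0.94), a reading frame that overlaps RSC2, so their reads are not told apart. The ribosome biogenesis genes had a median of -0.25 (41 genes) and the intron-containing genes, many of which encode ribosomal proteins, a median of -0.25 (153 genes), both below all random lists. The highest were short genes: QCR10, a subunit of respiratory complex III (1.17, counting interval 0.73 to 1.62, but 0.53 without division by extract), COA6 (0.98), MED11 (0.90), YBR085C-A (0.87) and MEO1 (0.83). Median changes were 0.17, 0.015, -0.063 and -0.17 from the lowest to the highest quartile of wild-type RNA, and 0.12 in the 198 genes within 20 kb of a chromosome end.

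**Figure D3:**
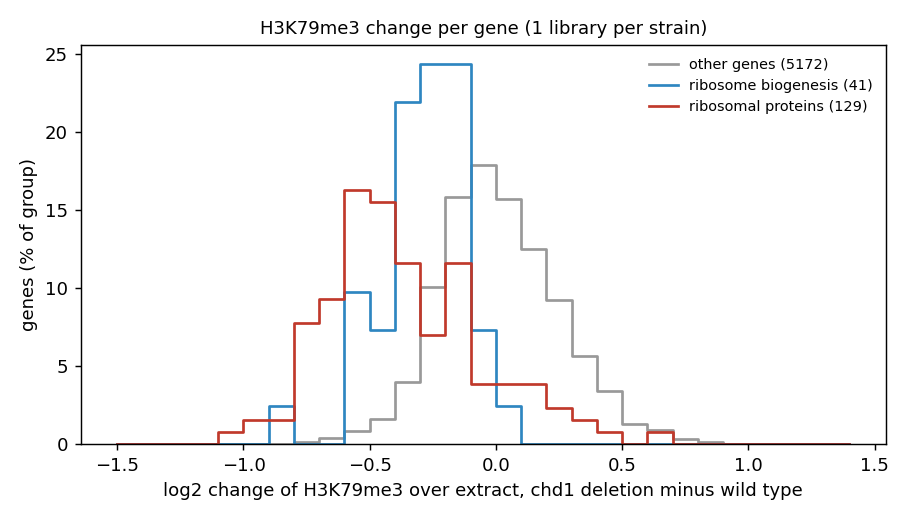
Distribution over genes of the log2 change of H3K79me3 over extract (chd1 deletion minus wild type, horizontal axis) as a percentage of each group (vertical axis), with 1 library per strain. Ribosomal protein genes (129 genes, median -0.41) and ribosome biogenesis genes (41 genes, median -0.25) lie to the left of the other genes.

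Genes whose marks differed between the strains tended to differ in RNA in the same direction. Across 5155 genes the H3K4me3 change and the RNA change had a Pearson correlation of 0.353 and a Spearman correlation of 0.383, and across 5079 genes the H3K79me3 change and the RNA change had 0.381 and 0.420. AIM11 was an example, with an RNA log2 fold change of 1.15 (SE 0.22) that did not pass over all genes, while RPO21 had an RNA log2 fold change of -0.12 beside its H3K4me3 change of -1.61. The changes of the 2 marks correlated across 5294 genes (Pearson 0.516, covariance 0.0368). Both marks were divided by the same extracts, and simulated libraries with no change gave a Pearson correlation of 0.350 and a covariance of 0.00613. The level of H3K79me3 over genes followed wild-type RNA per bp with a Spearman correlation of 0.255 in the wild type, and in the deletion it followed its own RNA with 0.0884, while H3K4me3 had 0.558 and 0.468. Genes are not independent replicates, so these 7 correlations across genes carry no p-value.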

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

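The tests of fragment length, of dilution, of ribosomal protein genes matched on RNA level or length, of nucleosome loss at these genes, and of stress genes against the spread between replicates were chosen after the results were seen. The test in genes low in H3K4me3 was set before its result was seen.

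Reads outside the nuclear chromosomes were not part of the comparisons and stood above the limit that a count of 0 allows. The 2-micron plasmid, a yeast episome, made up 1.90% of extract reads in the wild type and 1.01% in the deletion, 1.22% and 0.766% of H3K79me3 reads, and 1.63% and 0.949% of H3K4me3 reads. In RNA it made up 0.132% and 0.0947% of reads in the wild-type libraries and 0.0744% and 0.0748% in the deletion libraries. Mitochondrial DNA made up 7.12% of extract reads in the wild type and 6.71% in the deletion, and ribosomal DNA 8.65% and 7.53% of nuclear extract reads. Inside the deleted CHD1 gene, the deletion libraries held 122 reads for H3K79me3 (2.77% of the wild type at equal depth, exact 95% interval 2.30 to 3.32) and 30 for H3K4me3 (2.19%, 1.47 to 3.14), above the 0.669% of the extract.

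H3K79me3 lay nearer to gene starts in the deletion, and the tables argue against 2 technical accounts as its only cause. With the reads of each library moved by that library's own strand lag (141 to 178 bp), the difference in the median share of the first 500 bp was 5.71 percentage points. Displacement of reads by different fragment lengths therefore does not explain it. Moving reads corrects only their position, so other effects of fragment length were not tested. A weaker pull-down alone would have drawn enrichment toward 1 everywhere, but in the first 500 bp, where the wild type was already above 1, the log2 ratio was 0.20. From 150 to 100 bp upstream of the start codon enrichment did lie nearer to 1 in the deletion (0.663, against 0.520 in the wild type). Some dilution beside another cause is not excluded. Mitochondrial reads, which would rise with unbound DNA, made up 1.64% of H3K79me3 reads in the wild type and 2.65% in the deletion. In the extracts they made up 7.12% and 6.71%. Fragments that carry H3K4me3, caught through cross-reaction of the antibody, cannot be told apart from a shift of H3K79me3: in the 836 genes with the lowest wild-type H3K4me3 the difference was 3.42 percentage points (2.62 to 3.84), smaller than over all genes. A change in where H3K79me3 is laid down without Chd1, or in where nucleosomes sit, may also account for it and was not tested.

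H3K79me3 was lower over ribosomal protein genes in the deletion. Matching on wild-type RNA level alone, in 20 bins, did not account for it. The list's median of -0.41 lay at percentile 0 of random lists so matched (random median -0.11). Matching on length alone did not either, at percentile 0 of such lists (random median 0.076). RNA level and length were not matched together. The median change fell from 0.17 in the lowest to -0.17 in the highest quartile of wild-type RNA, so a part played by RNA level is not excluded. A loss of nucleosomes from these genes could lower the signal of any mark, and remains open. Over the same coding regions H3K4me3 had a median change of -0.46 (interval from resampling the 129 genes -0.53 to -0.41), against -0.0080 over all genes. Random lists matched on wild-type RNA level had a median H3K4me3 change of -0.23, so part of that fall goes with RNA level. In the window around the start codon, which reaches upstream, the H3K4me3 median of the ribosomal protein genes was -0.051. Unmodified H3 was not measured, so a loss of nucleosomes cannot be set against a lower level of both marks per nucleosome. Loss of Chd1 acting on these genes stays a hypothesis.

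Stress genes stood higher in RNA of the deletion. The mean log2 score of the 31 genes was 5.22 and 5.17 in the wild-type libraries and 6.09 and 5.66 in the deletion libraries. The gap between the strains, 0.68, was 1.55 times the larger gap between replicates, 0.44 in the deletion. With 2 libraries per strain an effect of the deletion cannot be told apart from cultures that had used up more of their medium, which could raise the same genes.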

How the results depend on the processing

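Of the alternatives 3 were added after the data were seen, among them limma-trend and the one on chromosomes with no anchor run left out, and the others were planned. Also planned, but not run, was a correction for GC content and length with the block, since no sequence of the build was given. Another count test was planned and not run either. The plan set limma-voom for files of alignments with no count column, though the reads counted per gene would have allowed a count model. CHD1 and YGP1 were called under each of the 11 other settings. The count of changed genes, 2, was 7 (5 higher, 2 lower) with 1 read per position, 5 (3 higher, 2 lower) with windows shortened by 50 bp, 3 (2 higher) with limma-trend, and 2 with median-of-ratios factors, no filter or overlapping genes left out. Leaving out 1 library gave 2 to 17 changed genes and 1 to 16 higher genes, in fits where the lone library is assumed to vary like the others. Beside CHD1 and YGP1, YRO2, BNA2, BNA4, YGR201C and HOM3 were called with 1 read per position, YRO2, YGR201C and HOM3 with shortened windows, YGR201C with limma-trend, TIR1, BNA4 and NCA3 without wild-type replicate 1, YRO2 without deletion replicate 1, and YRO2, HSP30, STF2, SPI1, CIP1, HOR7, RTC3, YGR201C, TIR3, ZRT1, YPC1, TDA6, TDH1, GSY1 and TPO4 without deletion replicate 2. The replicate block gave 12 changed genes (9 higher, 3 lower) and 2 genes with a changed intron share. With a preset correlation of 0.01 it gave 11 called gene lists against 9 (the iron regulon, camera adjusted p = 0.00757, and a-cell markers, 0.0259, were added). The block added TDH1, YRO2, ZRT1, ARN2, BNA4, YGR201C, RTC3, YDR222W, HOM3 and BNA5 to the RNA calls. With 2 pairs that share only a number (correlation of replicate differences 0.325), that result is given for comparison only. The median difference of 3' to 5' reads, 0.022, was 0.045 in the outer 500 bp of genes of at least 2000 bp and ran from 0.0044 to 0.037 with 1 library left out. The median intron difference, -0.42, was -0.057 without ribosomal protein genes.

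Of 635 values of named genes in RNA, 598 kept their direction and side of the threshold and 36 changed sign; of 99 values of the 9 gene lists called in the main fit, 88 were kept, while the number of lists called ran from 7 to 12. Ranges with 1 library left out that crossed 0 were -0.17 to 0.055 for ribosomal proteins, -0.31 to 0.0081 for cell cycle regulators, -0.29 to 0.17 for UBP10, -0.14 to 0.065 for HTB2, -1.55 to 1.54 for PHO84, -1.21 to 0.90 for VTC3, -0.29 to 0.13 for PDC1, -0.12 to 0.033 for BAR1, -0.13 to 0.068 for STE4, -0.55 to 0.0029 for FET3, -0.11 to 0.026 for GLN1, -0.26 to 0.16 for CTS1, -0.33 to 0.18 for EGT2, -0.13 to 0.075 for COS6, -0.23 to 0.0092 for CAN1, -0.18 to 0.12 for RAP1, -0.077 to 0.13 for HST1 and -0.070 to 0.17 for RPL30. With 1 read per position the sign also changed for HTB2 (0.019), VTC3 (0.085), RPL3 (0.0061), NOP1 (0.0063), PDC1 (0.0077), BAR1 (0.033), GLN1 (0.042), ERG3 (0.034), CTS1 (0.021), COS6 (0.083) and RAP1 (0.036). None of these genes was called. The cause was not tested.

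No ChIP value changed sign, but 32 of 42 log2 ratios by region lay outside the resampling interval of the main value. The log2 ratio of H3K4me3 in the last 500 bp, 0.10, was 0.23 in genes of at least 2000 bp. The difference in the H3K4me3 share, -1.60, was -1.02 with 1 read per position, -2.52 without division by extract, -3.19 in genes of at least 2000 bp, -2.11 without close divergent neighbours and -1.12 on the chromosomes with no anchor run left out (1410 genes). The difference in the H3K79me3 share, 5.81, was 4.84, 4.99 and 4.48 in the first 3 of these and 5.80 in the last. The SD of the change per gene was 0.24 with 1 read per position, 0.27 without division by extract and 0.26 with at least 300 reads for H3K4me3, and 0.21, 0.22 and 0.23 for H3K79me3. Without division by extract the Spearman correlation with RNA was 0.478 for H3K4me3 and 0.464 for H3K79me3. The cause was not tested. In simulated RNA libraries at the depth and the spread seen, 2-fold changes were recovered in 82.2% of cases and 1.5-fold changes in 23.4%. Those libraries held 200 genes changed independently, which makes the adjusted threshold easier to pass than in the main fit with 2 calls. The rates are therefore not rates for the real libraries, where TIR1 at log2 1.71 had a limma-voom adjusted p of 0.215. Depth and spread were not varied apart, so which of them limits the calls was not tested.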

Other observations

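The genes below, apart from YGP1, were chosen after their values were seen, and none of those chosen so passed the threshold over all genes in the main fit. Some passed in other fits, among them YRO2 with 1 read per position, with shortened windows and without either deletion library, BNA2 with 1 read per position, BNA4 with 1 read per position and without wild-type replicate 1, and ZRT1 without deletion replicate 2. Of the genes of NAD synthesis from tryptophan, which were not tested as a group, BNA2 had a log2 fold change of 2.13 (SE 0.29, limma-voom adjusted p = 0.121), BNA4 1.65 (SE 0.22), BNA1 1.28 (SE 0.21) and BNA5 0.83 (SE 0.12), each with both deletion libraries above both wild-type libraries. BNA6, the last enzyme specific to that route, had 0.039 (SE 0.11), BNA7 0.53 (SE 0.15) and BNA3 -0.025 (SE 0.16). TNA1, the nicotinic acid transporter, went from 528 ± 60.5 to 977 ± 225 CPM (SD, n = 2 per strain), and NPT1, of the salvage route, from 313 ± 14.6 to 228 ± 18.3 CPM.

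Other genes with large differences were YRO2, a membrane protein gene (log2 2.52, SE 0.30, limma-voom adjusted p = 0.0735), ZRT1, the high-affinity zinc transporter (1.41, SE 0.23), and the glycerol synthesis genes GPD1 (0.87, SE 0.15) and GPP2 (1.05, SE 0.20). YGP1, the gene that rose in RNA, had an H3K4me3 enrichment of 0.581 in the wild type and 1.02 in the deletion, and an H3K79me3 enrichment of 0.905 and 0.856.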
